A study of Mus musculus with 12 samples.

How the data were processed

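Gene expression was measured in 12 samples of mouse cerebellum (C57BL/6, postnatal day 3) in 4 groups of 3. Every animal carried Math1-Cre, a recombinase active in the granule cell lineage of the cerebellum, so floxed genes were deleted in that lineage and RNA from all other cell types stayed intact. BaxBak controls carried floxed Bax and lacked Bak, a pair of genes whose proteins open the mitochondrial outer membrane in apoptosis. Atr BaxBak mutants carried floxed Atr in addition, the gene of a kinase that responds to replication stress. The p53 controls carried floxed p53 (Trp53), and the Atr p53 mutants carried floxed Atr as well. Per the labels' protocols, meninges were removed, RNA was extracted on RNeasy columns, and 500 ng of total RNA per sample was made into biotin-labelled sense-strand cDNA with the Affymetrix WT PLUS kit. A label also describes the samples as poly-A selected. No label says that the samples of a group came from separate litters, and p-values measure the spread between these samples.

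Values were taken as the authors deposited them. The deposited value table holds log2 signals per probe set, not per gene. Each probe set covers an exon region or an exon junction. Partek is named in the submitters' processing notes without a role or version. The background correction, the summary of probes, the normalization and the build of the array annotation are not given in the sources used here. Medians of the 12 arrays lay between 6.46 and 6.49, so the arrays were taken to be normalized against each other. Of 725678 probe sets, 61 had no values and 6546 were controls, which left 719071 for testing (437027 exon regions and 282044 junctions). A second deposited table of log2 values had 15607 of its 16378 probe sets in common with the first, with identical values, and was not used further. A pair of authors' deposited tables gives fold changes, p-values and step-up adjusted p-values for 34305 probe sets. All of these probe sets have a step-up p under 0.05 in the authors' BaxBak comparison, and the table of the p53 comparison holds the same ones. The authors' fold values equalled the group differences in the value table to within 9.27e-05 on the log2 scale.

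Gene symbols were taken from those authors' deposited tables, which name 31628 of the exon and junction probe sets. Of these, 709 with more than 1 symbol were left out, and 30919 probe sets of 7912 genes were used. Each gene is the mean of its named probe sets. A single probe set stood for 3827 of the genes, the median was 2, the maximum 67, and 109 genes had the same values as another gene. Symbols that a spreadsheet had turned into dates were restored from the annotation column for 16 probe sets. A probe set is named only if it passed the authors' test in the BaxBak comparison. Gene values in that comparison, in the difference between backgrounds and in a contrast of the control groups were therefore selected on these samples. Gene values in the p53 comparison were not selected on that comparison. Its tests of named genes are not free of selection, however. Naming favours probe sets with a small spread in the BaxBak samples, and the fit shares its spread over all 12 samples. A RefSeq gene table (GRCm38.p6) matched 7182 of the 7912 symbols and served for aliases and gene order only. The chromosome code in the probe set identifiers equalled the RefSeq chromosome for 99.89% of matched named probe sets.

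The tests were planned for gene-level values, and the unit found here led to a fit per probe set beside a fit per named gene. Both used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with 1 mean per group over all 12 samples and 8 residual degrees of freedom. The contrasts were Atr BaxBak mutants minus BaxBak controls, Atr p53 mutants minus p53 controls, and the first minus the second. P-values were adjusted by the Benjamini-Hochberg method over all probe sets or all named genes, with a threshold of 0.05. In the BaxBak comparison a gene was called higher or lower if its mean passed and at least 1 of its probe sets also passed over the whole array in that direction and none in the other. In the p53 comparison a gene was called if its mean passed. In the difference a gene was called if at least 1 of its probe sets passed over the whole array and none the other way. A gene whose means in both groups compared lay under those of the negative controls is given no fold. Where 1 group did, the fold is a lower bound, the other group's mean against the mean, per array, of the higher of the negative control mean and the gene's own value. The bound makes no allowance for a difference in negative control signal between the groups. Both limits were set after values were seen. Errors given after ± are standard errors of limma's log2 fold changes unless marked SD.

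Before the data were examined, 24 gene lists were fixed, 13 of them for pathways and sex and 11 for cell types of or around the cerebellum. The 18 lists with at least 3 named members were tested with limma's camera with a preset correlation of 0.01, adjusted over lists. Genes named in the text follow a rule also fixed beforehand: the genes the genotypes alter, the 10 most raised and 10 most lowered called genes whose 3 mutant values all lay beyond the 3 control values, the 5 largest differences each way, and up to 4 members per list with the smallest p. Atoh1 and Otx2 each stand on 2 lists, and all the cell types listed can be part of the dissected tissue. Some list members that the rule selects are counted in their lists and not reported here by name. Predicted genes, clones, small RNAs and sex-linked genes were counted and not named. Because many of those genes rested on 1 probe set, the same rule was run again on genes with at least 3 probe sets. That addition, a list of 33 early embryonic genes, the histone genes, the contrast of the control groups and the other genes singled out below were chosen after values were seen.

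The fit was tested on simulated data with the real spread. At a log2 change of 1, 36.5% of changed probe sets were recovered in the BaxBak comparison, 41.0% in the p53 comparison and 10.5% in the difference. At a log2 change of 2 the shares were 83.5%, 82.0% and 63.5%. For named genes in the p53 comparison, 87.5% were recovered at 0.5 and 97.5% at 1. Without a simulated change, 0 of the 18 lists were called in the p53 comparison, but the simulation holds no correlation between genes, and other groupings of the real samples called 1 to 7 lists in the p53 and 8 to 12 in the BaxBak comparison. The number of arrays limits the precision. Alternatives covered normalization, filters on dim probe sets, the spread model, array weights, sex (3 samples without Y-chromosome signal), the label prefix, the way probe sets were joined to genes, gene set tests and leaving out each sample. The negative control signal as a covariate and a filter on probe sets below that signal were added after seeing the data. Figures were drawn with matplotlib 3.10.9.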

Results

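Whole cerebella of 12 mice at postnatal day 3, when granule cell precursors still divide in the outer layer, were profiled on exon and junction arrays. The 4 groups of 3 samples were BaxBak controls, Atr BaxBak mutants, p53 controls and Atr p53 mutants. They pose the question of what loss of Atr in the granule cell lineage does to the cerebellar transcriptome when mitochondrial apoptosis is blocked and when p53 is absent. Each array gave log2 signals for 719071 probe sets, with medians between 6.46 and 6.49, and 76.2% of the probe sets had a mean above that of the negative control probe sets (4.27). On the first principal component (21.4% of the variance) the Atr BaxBak mutants lay between -243 and -165, and the other samples between -14.3 and 127.

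Trp53 was the targeted gene that could be followed. In the p53 controls, 4 of its 6 named probe sets, those assigned to 1 RefSeq transcript, were 0.51 to 0.96 lower on the log2 scale than in BaxBak controls (differences from -0.96 to -0.51), and the other two differed by -0.08 and 0.43. As a gene mean, Trp53 differed by -0.40 ± 0.06 between the control groups (adjusted p = 0.00306, limma). These 6 probe sets were named by a comparison that uses the same BaxBak controls. In Atr BaxBak mutants all 6 probe sets were higher than in their controls, by 1.38- to 1.92-fold, with a gene mean of 0.67 on the log2 scale. In Atr p53 mutants they stood at 1.02- to 1.15-fold (gene mean 0.11), and none passed the test. Probe sets outside the deleted part do not report the deletion, and the sources used here do not say which lie inside it. Atr, Bax and Bak1 had no named probe set and were not analysed here. Names exist only for probe sets that passed the authors' BaxBak comparison, in which the mutants carry floxed Atr. Among the probe sets listed as passing, none carried Atr as its only symbol, so no fall of Atr RNA was seen there. A fall in probe sets without a name would be missed. The deletion of Atr was therefore not shown in these data, and its loss is taken from the genotype labels.

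In the BaxBak background, p53 target genes and markers of glia, Purkinje cells and interneurons were higher in Atr mutants than in controls, and genes of DNA replication, mitosis and DNA repair were lower. These list calls were made with a preset correlation, and none held with an estimated correlation (adjusted p = 0.253 to 0.383). The Atr BaxBak mutants share a label prefix that no other group holds, so genotype and what that prefix marks cannot be told apart. The death receptor gene Fas rose 5.22-fold (log2 2.38 ± 0.07, 12 probe sets, from a control mean of 4.26, close to the negative controls at 4.11) and the cell cycle inhibitor gene Cdkn1a rose by 1.48 on the log2 scale. The mitotic checkpoint kinase gene Bub1 was 2.90-fold lower (-1.54 ± 0.12, 48 probe sets). Over the array, 15996 probe sets were higher and 21684 lower, together 5.24% of those tested, and 21.6% had an unadjusted p under 0.05. By name, 2488 genes were higher, 3657 lower, 252 had probe sets going both ways and 1515 did not pass. Names exist only for probe sets that passed the authors' own test of this comparison, so the counts of named genes and list members here are not independent evidence of direction. The authors' deposited table lists 13304 probe sets higher and 21001 lower.

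Of the 36 named p53 target genes, 31 were higher and 3 lower in Atr BaxBak mutants (32 and 4 adjusted over the list alone), with a median fold of 1.92. With Fas and Cdkn1a, the members with the smallest p were the xylulose reductase gene Dcxr (1.32 ± 0.06) and the T cell costimulator gene Cd80 (2.38 ± 0.13, and 0.97 on its brightest probe set). The lower members were Rrm2b (-0.53), Bloc1s2 (-0.83) and the locus of the Tigar gene (-0.77). The camera adjusted p was 1.63e-09, and the adjusted p = 0.253 with an estimated correlation. Mean list scores lay between 0.877 and 0.950 in the 3 mutants and between -0.063 and 0.038 in the controls (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The negative control probe sets were also brighter in these mutants, by 0.325 on the log2 scale.

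Replication and mitosis genes fell together. All 40 G1/S and replication genes were named, and 39 were lower (40 adjusted over the list alone), with a median of -0.95. They included the thymidylate synthase gene Tyms (-1.20 ± 0.07), the clamp loader gene Rfc5 (-0.92), the primase gene Prim1 (-1.07) and the replicative helicase gene Gins2 (-0.83). Among 37 named G2/M genes, 36 were lower (37 adjusted over the list alone), with a median of -0.95. The cohesin protector gene Sgol1 stood at -1.69 ± 0.12, the kinetochore gene Nuf2 at -1.17, the cyclin-dependent kinase gene Cdk1 at -1.07 and the passenger complex gene Birc5 at -0.78. The camera adjusted p was 4.63e-07 for the first list (adjusted p = 0.344 with an estimated correlation) and 1.71e-06 for the second (adjusted p = 0.383 with an estimated correlation). With the negative control signal as a covariate, chosen after seeing the data, the medians were -0.77 and -0.71. Markers of other cell types rose in the same samples (values given with those lists).

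DNA repair genes moved the same way. Of 23 named homologous recombination and Fanconi genes, 22 were lower and 1, Rad52 (0.52), was higher, with the same numbers adjusted over the list alone. The median was -0.85, and the resection nuclease gene Exo1 stood at -1.22 and Eme1 at -0.89 (camera adjusted p = 0.000229, and adjusted p = 0.344 with an estimated correlation). Of 19 named checkpoint and damage signalling genes, 17 were lower and 1 higher (18 and 1 adjusted over the list alone), with a median of -0.57. The checkpoint adaptor gene Clspn stood at -1.09, the kinase gene Chek1 at -0.93, Tipin at -0.88 and Chek2 at -0.69, while the ubiquitin ligase gene Rnf8 stood at 0.89 on 1 probe set (camera adjusted p = 0.00463, and adjusted p = 0.344 with an estimated correlation). Replication genes fell and negative control signal was higher in the same 3 samples.

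Named granule cell precursor genes were lower, and later granule neuron genes went both ways. The granule cell precursor, Shh response and postmitotic granule neuron lists held 18, 15 and 25 genes, of which only named members are counted. Of 8 named granule cell precursor genes, 6 were lower and 0 higher (8 lower adjusted over the list alone), with a median of -0.55. Pax6, a transcription factor gene of the lineage, stood at -0.72 ± 0.08, Barhl1 at -0.66, Meis1 at -0.46 and Zic4 at -0.39. The camera adjusted p was 0.0436 (adjusted p = 0.447 with an estimated correlation), and 0.0829 with the negative control covariate. Of 8 Shh response genes, 5 were lower and 1, Nkx2-2, was higher (6 and 2 adjusted over the list alone), with Ccnd1 at -1.29, Sfrp1 at -1.02, Mycn at -0.59 and Atoh1, the gene whose regulatory sequence drives the Cre, at -0.64, a median of -0.61 and a camera adjusted p of 0.474. Of the postmitotic granule neuron genes, 4 of 10 were higher and 3 lower (6 and 4 adjusted over the list alone). The contactin gene Cntn1 stood at 0.95 and Tcf4 at 0.86, against Cdkn1b at -0.65 and Gap43 at -0.54 (median 0.33, camera adjusted p = 0.356).

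Named markers of astrocytes, oligodendrocytes, Purkinje cells, GABAergic interneurons and vessels were higher. These lists held 17, 15, 16, 11 and 15 genes in that order, and only members with a named probe set are counted. Of 10 astrocyte and Bergmann glia markers, 9 were higher (10 adjusted over the list alone), with a median of 0.77, among them Gja1 (1.34), Aqp4 (1.03), Slc1a3 (0.91) and Gdf10 (0.84). Of 11 oligodendrocyte lineage markers, 10 were higher (10 higher and 1 lower adjusted over the list alone) with a median of 0.85 and with Sox10 at 0.85 and Cspg4 at 0.65, while Pdgfra had probe sets going both ways. All 7 named Purkinje cell markers were higher, also adjusted over the list alone, with a median of 0.74, among them Pcp2 (1.34), Rora (0.74) and Gad1 (0.74), which interneurons also express. Of 9 GABAergic interneuron markers 7 were higher (9 adjusted over the list alone), with a median of 0.66, among them Gad2 (0.77), Slc6a5 (0.74) and Pax2 (0.69). Of 5 endothelial and pericyte markers 3 were higher (5 adjusted over the list alone), with a median of 0.57 and Vwf at 0.77. Camera adjusted p-values were 0.000683, 0.00215, 0.00117, 0.00103 and 0.0219 in that order. In the same order, the adjusted p = 0.253, 0.344, 0.285, 0.285 and 0.344 with an estimated correlation.

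Other lists were not called in this background. The microglia, unipolar brush cell, interferon, apoptosis and stress lists held 22, 6, 28, 20 and 20 genes, of which only named members are counted. Of 6 microglia markers 3 were higher and 1, Mrc1 (-0.63), was lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0907). Of 3 unipolar brush cell markers, 2 were lower, Eomes (-0.73) and Otx2 (-0.82), and 1 was higher, also adjusted over the list alone (camera adjusted p = 0.731). Of 7 interferon and cytosolic DNA response genes, 5 were higher, including Usp18 (0.92), Irf9 (0.86) and Ifi27, which lay under the negative controls in both groups, and Ifit2 (-0.73) and Stat2 (-0.49) were lower, with the same numbers adjusted over the list alone (camera adjusted p = 0.0907). Of 9 apoptosis genes 3 were higher and 4 lower (3 and 6 adjusted over the list alone), with Bcl2l11 at 0.67 and Bok at -0.72 (camera adjusted p = 0.726). Of 8 heat shock, hypoxia and stress genes 4 were higher and 2 lower (4 and 3 adjusted over the list alone), with the stress transcription factor gene Atf3 at 0.93 and Vegfa at 0.78 (camera adjusted p = 0.397). Lists with fewer than 3 named members were not tested. They gave Socs3 (-0.53) and Ptgs2 (0.43) for inflammation, Col1a1 (-0.98) and Bgn (at least 1.63-fold higher, from a control mean under the negative controls) for meninges and fibroblasts, Otx2 for choroid plexus, Epb4.2 (0.47) for erythroid cells, Hoxb3 (-0.98) for brainstem and 0 sex-linked genes. The Bgn bound makes no allowance for the brighter negative controls of the mutant arrays (Bgn mutant mean 4.83 against 4.43).

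**Figure D1:**
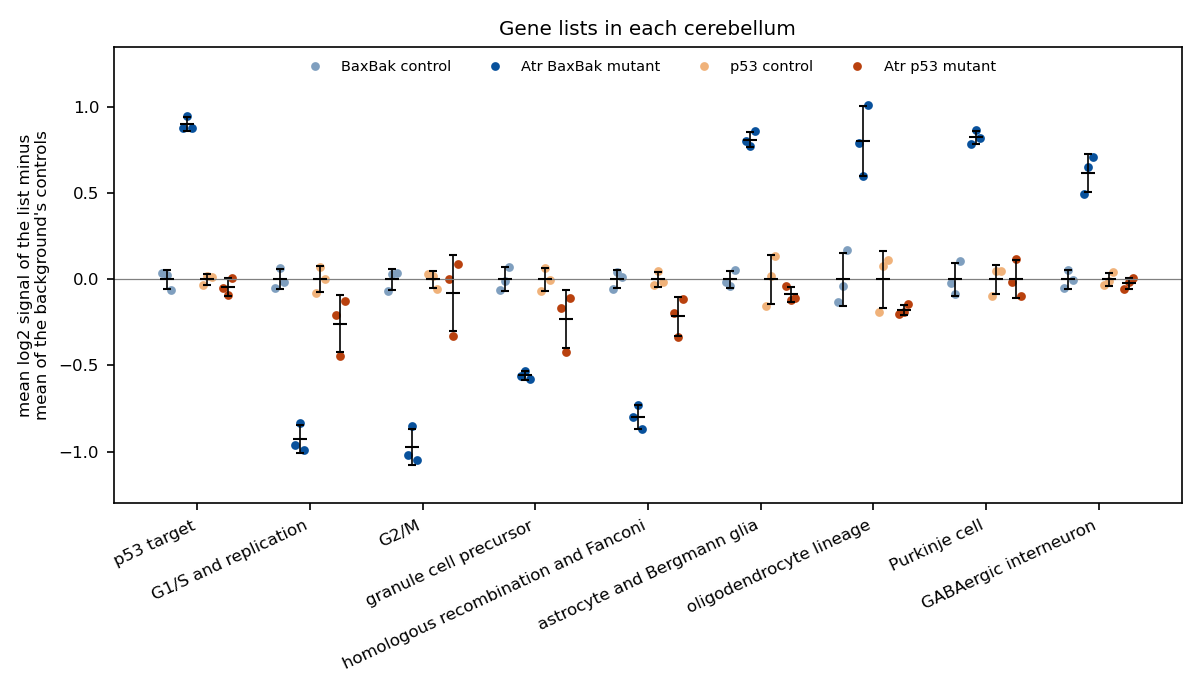
Mean log2 signal of each gene list in each cerebellum, with the mean of that background's controls set to 0 (y axis), for 9 lists (x axis) and the 4 groups (colours). Points are samples, horizontal marks are group means and bars are SD (n = 3). For p53 target genes the Atr BaxBak mutants averaged 0.902 and the Atr p53 mutants -0.045, and for G1/S genes they averaged -0.928 and -0.259 (-0.166 without Atr p53 mutant 2).

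By the rule for named genes, the most raised genes in the BaxBak background included 5 members of the Zscan4 family, zinc finger genes known from early embryos and embryonic stem cells. Their control means lay between 2.73 and 3.52, under the mean negative control signal, so their folds are lower bounds. These bounds make no allowance for the brighter negative controls of the mutant arrays (4.43 against 4.11 in controls). Zscan4c rose at least 5.71-fold, Zscan4d at least 4.97-fold, Zscan4f at least 3.17-fold, Zscan4b at least 2.53-fold and Zscan4e at least 2.42-fold. Each shared probe sets of identical values with other members, so they are not 5 separate measurements. The others were Rgs12 (at least 3.64-fold), Usp14 (2.92 on the log2 scale, as are the other values in parentheses not given as folds) and March6 (2.75), each on 1 probe set, and Pde6a (2.78, from controls at the level of the negative controls) and the epidermal transcription factor gene Zfp750 (2.45). The most lowered were the spindle augmin gene Haus2 (at least 4.17-fold), Rbm28 (at least 4.59-fold), Frmd5 (-2.40), Yipf3 (at least 1.31-fold), Arhgef10 (-2.06), Rmdn3 (-2.02), the urea cycle gene Otc (at least 3.51-fold), Fam63b (from a control mean of 8.10 to 6.10), Rab32 (at least 1.10-fold) and Ubr1 (-1.97). The folds of Haus2, Rbm28, Yipf3, Otc and Rab32, and of Tex14 and Cd36, are bounds because their mutant means lay under the negative controls. Yipf3, Arhgef10, Rmdn3, Fam63b and Rab32 rested on 1 probe set. On the brightest probe set, Frmd5, Atr effect in the BaxBak background, stood at -0.40, and Ubr1, Atr effect in the BaxBak background, at -0.59. For March6 and Arhgef10 the BaxBak controls (5.01 and 6.73) stood apart from the 3 other groups, with Atr BaxBak mutants at 7.76 and 4.68 and p53 controls at 8.15 and 4.45. With at least 3 probe sets, a requirement chosen after values were seen, the leukotriene synthesis gene Alox5 (2.32 ± 0.07, 32 probe sets) and Usp17le (2.38) joined the top, at 1.13 and 0.69 on their brightest probe sets. The lowest then included Tex14 (at least 1.63-fold), Cd36 (at least 1.94-fold), Zfp106 (-1.59), Usp44 (-1.52) and the cohesin acetyltransferase gene Esco2 (-1.51), and Zfp106, Atr effect in the BaxBak background, stood at -0.38 on its brightest probe set. Over the whole array the brightest probe sets of Frmd5 and Zfp106 did not pass (adjusted p = 0.061 and 0.066). Gene adjusted p-values of all genes in this paragraph were at most 0.00018 (limma). For the Atr effect in the BaxBak background, the count of 37680 probe sets was 15943, 7554 and 14828 without BaxBak controls 1, 2 and 3, and 12013, 15664 and 10334 without Atr BaxBak mutants 1, 2 and 3. The negative control covariate lowered it to 759.

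In the p53 background fewer probe sets differed between Atr mutants and controls. Hist1h4k, a histone gene, was 3.16-fold higher (1.66 ± 0.09, 1 probe set). Snhg5, a small RNA host gene, ranked above it, but its means in controls (1.94) and mutants (4.27) lay under those of the negative controls (4.23 and 4.30), so no fold is given. The Wnt antagonist gene Sfrp1 was lower (-0.72 ± 0.15, 6 probe sets), although its brightest probe set (-0.56) did not pass. Over the array 17 probe sets were higher and 15 lower, and 7.76% had an unadjusted p under 0.05. Of the named genes, 89 were higher and 103 lower, tested with a spread estimated partly on the samples that selected the names. Of the 34305 probe sets in the authors' deposited table, 2 (in Hist1h4k and Stat6) had a step-up p under 0.05, and 19.98% had an unadjusted p under 0.05.

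None of the p53 target genes was called in this background (0 of 36, also 0 adjusted over the list alone), and their median was -0.06. Cdkn1a stood at 0.03 on the log2 scale, and Fas lay under the negative controls in both p53 groups. G1/S and replication genes had a median of -0.28, with 38 of 40 below 0. The thymidine kinase gene Tk1 (-0.34, adjusted p = 0.049) passed over all named genes, and 19 passed adjusted over the list alone. Among those with the smallest p, Cdc6 stood at -0.52, Pola1 at -0.38 and Rfc5 at -0.23. For homologous recombination and Fanconi genes the median was -0.24, with Fancm (-0.28) lower over all named genes and 12 of 23 lower adjusted over the list alone. Fancd2 stood at -0.43, Brip1 at -0.41 and Xrcc2 at -0.35. Granule cell precursor genes had a median of -0.22, with 0 of 8 called over all named genes and 4 lower adjusted over the list alone. The camera adjusted p-values of these 3 lists were 6.09e-07, 7.27e-05 and 0.0146, and the adjusted p = 0.730, 0.730 and 0.803 with an estimated correlation. Scores of the G1/S list were below all controls in the 3 mutants, at -0.445 in Atr p53 mutant 2 and at -0.206 and -0.126 in the others. Without mutant 2 the mean score moved from -0.259 to -0.166 for G1/S and from -0.232 to -0.136 for granule cell precursor genes. That sample was the only one of the p53 groups without Y-chromosome signal, and its negative controls (4.50) were the brightest of the 6.

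G2/M genes did not pass in the p53 background (0 of 37, also 0 adjusted over the list alone), with a median of -0.10 and a camera adjusted p of 0.609, and their mean score turned from -0.079 to 0.045 without Atr p53 mutant 2. Checkpoint genes had a median of -0.12 (0 of 19 called, camera adjusted p = 0.190). Without that sample the mean scores of checkpoint and Shh response genes moved from -0.123 to -0.066 and from -0.271 to -0.159. Of the cell type lists none was called, with medians of -0.11 for astrocyte and Bergmann glia, -0.21 for oligodendrocyte lineage, 0.01 for Purkinje cell, -0.02 for GABAergic interneuron, -0.11 for endothelial, -0.10 for microglia and -0.07 for unipolar brush cell markers. Shh response (-0.37), postmitotic granule neuron (-0.003), apoptosis (-0.15), interferon (-0.05) and stress genes (0.09) were not called either. Sfrp1 in the first of these 5 lists and Atf3 in the last (0.50 ± 0.09, adjusted p = 0.0193, limma) passed as single genes. For Atf3, Atr effect in the p53 background, the value was -0.0703 on its brightest probe set.

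Further named genes that rose in the p53 background were the lectin gene Cd209c (1.39), the ceramide synthase gene Cers2 (at least 2.16-fold), Sim1 (0.93), Trim66 (0.89 ± 0.11, 11 probe sets) and Dnaic1 (0.87). Genes that fell were Lrrc1 (-1.10), the G protein subunit gene Gnb5 (-1.09 ± 0.09), Nuggc (at least 1.47-fold), Hs1bp3 (-0.80), Ppp2r3a (at least 1.56-fold), Evi5 (-0.74) and Cbwd1 (-0.69). The rule also took Rasal3, Cd2 and Usp34 as higher and Zfp595 and Apobec3 as lower, but both group means of each lay under the negative controls, so their folds are not given. The control mean of Cers2 and the mutant means of Nuggc and Ppp2r3a also lay under them, so these folds are bounds. Cers2, Sim1, Lrrc1, Nuggc, Hs1bp3 and Ppp2r3a each rested on 1 probe set. With at least 3 probe sets, Slc7a3 (0.68) and Plekha1 (0.36) were also higher, and Cog7 (-0.57), Myo6 (-0.54), the somatostatin receptor gene Sstr2 (-0.49), Tead2 (-0.38) and the mitotic inhibitor gene Fbxo5 (-0.36) lower. On their brightest probe sets Dnaic1 (0.08), Evi5 (-0.11), Plekha1 (0.20) and Fbxo5 (-0.31) did not pass, and Cd209c stood at 0.78 and Gnb5 at -0.37. Over the whole array the brightest probe sets of Cd209c and Gnb5 did not pass either (adjusted p = 0.591 and 0.640, limma), although 1 other probe set of each did. Of the 11 probe sets of Trim66, 0 passed over the whole array. Snhg5, Lrrc1, Gnb5, Ppp2r3a and Myo6 lie on chromosome 9, the chromosome of Atr. For these genes, sequence differences linked to the Atr allele and an effect of losing Atr were not told apart. Of named genes called in the p53 background, 709 passed without Atr p53 mutant 3, 46 without mutant 2 and 79 without mutant 1. The count was 39 without p53 control 2, 36 without control 3, and 124 without Atr BaxBak mutant 1 or 2, against 192 with every sample. Among the samples that share a label prefix, p53 control 1 against the 3 mutants, 5 genes passed, where the lone control was assumed to vary like the other groups.

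The change from controls to Atr mutants differed between backgrounds by the test of the difference itself. The change in the BaxBak background minus that in the p53 background was higher for 317 probe sets and lower for 265, and 11.5% had an unadjusted p under 0.05. By name, 99 genes were higher and 117 lower. Names exist only for probe sets that passed the authors' BaxBak test, and the BaxBak change is part of this difference. Values of named genes and lists here were therefore selected on these samples and are not independent evidence of direction. The median difference of p53 target genes was 0.95, with 14 of 36 called higher (32 higher and 3 lower adjusted over the list alone). It was -0.88 for G2/M genes, with 13 of 37 called lower (37 adjusted over the list alone), and -0.67 for G1/S genes, with 6 of 40 called lower (38 adjusted over the list alone). Camera adjusted p-values were 2.34e-12, 1.50e-07 and 1.72e-06, and the adjusted p = 0.138, 0.342 and 0.342 with an estimated correlation. Among the genes with the largest called differences were Zfp750 (2.47 ± 0.17) and on the other side Fam63b (-2.52 ± 0.34), Frmd5 (-2.22), Ubr1 (-1.99) and Chodl (-1.84). Zscan4c, Zscan4f, Zscan4d and Pde6a were also called higher, but lay under the negative controls in both p53 groups, and Haus2 was called lower, but lay under them in Atr BaxBak mutants, so no sizes are given. Frmd5 and Ubr1 did not pass on their brightest probe set (-0.18 and -0.37). The backgrounds differ in p53 and in Bax and Bak together. The Atr BaxBak mutants also share a label prefix that no other group holds, and what it marks is part of this difference. In the difference of the Atr effect between backgrounds, the count of 582 probe sets was 281, 167 and 232 without BaxBak controls 1, 2 and 3, and 226 and 234 without Atr BaxBak mutants 2 and 3. It was 223, 1034 and 277 without Atr p53 mutants 1, 2 and 3, and 233 and 190 without p53 controls 2 and 3. With the negative control covariate it was 131, of which 77.1% were higher against 54.5%.

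Some genes moved in opposite directions. Cdkn3, a cyclin-dependent kinase phosphatase gene, stood at -0.67 in the BaxBak and 0.44 in the p53 background (4 probe sets), with a called difference. Ppp2r3a stood at 1.60 in the first and at least 1.56-fold lower in the second, and Evi5 at 0.54 and -0.74 (-0.11 in the p53 background on its brightest probe set, not called), both with a called difference. Hist2h2bb stood at -0.95 and 0.59, although for Hist2h2bb, Atr effect in the p53 background, the value was -0.0956 on its brightest probe set. Genes with nearly equal change in both included Trim66 (0.88 and 0.89) and Myo6 (-0.53 and -0.54), whose differences did not pass (adjusted p = 0.968 and 0.930, limma). Myo6 lies on chromosome 9, the chromosome of Atr, so for it linked sequence variants and a shared effect of losing Atr cannot be told apart.

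Across the 7912 named genes the 2 sets of log2 fold changes correlated with Pearson's r of 0.461 and Spearman's rho of 0.432, and 69.0% had the same sign. Over all 719071 probe sets, which were not selected on the BaxBak comparison, r was 0.216 and 58.3% had the same sign. These are correlations across genes, which are not independent replicates, and the comparisons share no samples. Of the 192 genes called in the p53 background, 169 (88.0%) had the same sign in the BaxBak background. Of the 17 probe sets higher in the p53 background 13 were also higher in the BaxBak background, against 0.378 expected of independent lists. Of the 15 lower ones 3 were also lower, against 0.452.

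**Figure D2:**
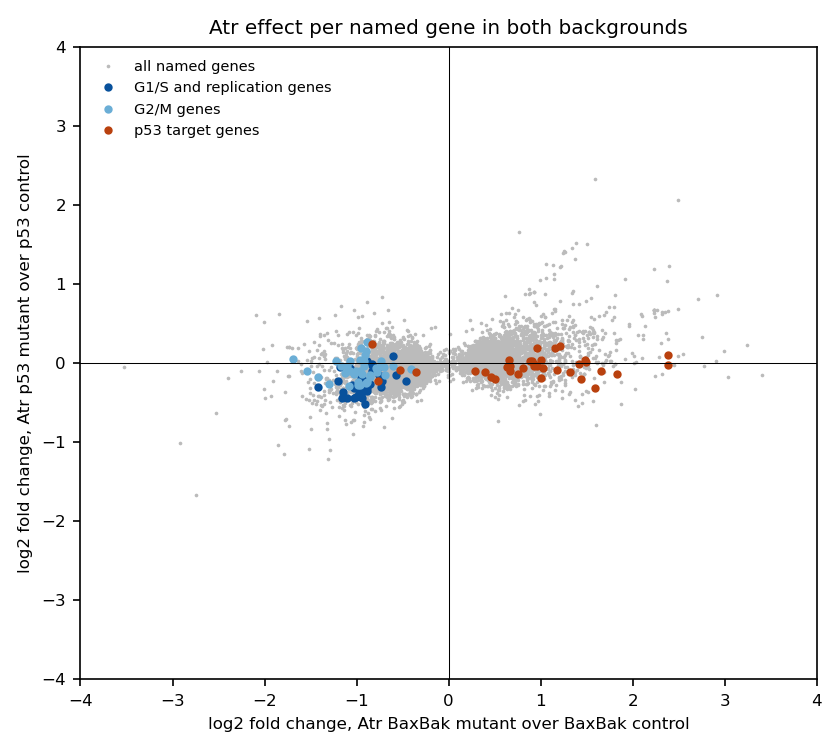
Log2 fold change of each of the 7912 named genes after loss of Atr in the BaxBak background (x axis) and in the p53 background (y axis). Each point is a gene, without error bars; p53 target genes (red) have medians of 0.94 and -0.06, and G1/S (dark blue) and G2/M genes (light blue) -0.95 and -0.95 on the x axis against -0.28 and -0.10 on the y axis. The gap at 0 on the x axis follows from the choice of named probe sets.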

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

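The tests on markers of other cell types, unipolar brush cell markers, the label prefix, and the chromosomes and the difference between backgrounds of the early embryonic genes were chosen only after the result was seen, as was the use of the negative control signal.

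The change from controls to Atr mutants differed between backgrounds by the interaction test. It was higher in the BaxBak background for 317 probe sets and lower for 265. What the label prefix of the Atr BaxBak mutants marks is part of this difference, since no other group holds it. Camera, which compares a list with the other genes, called 10 lists for this difference. Their median differences of gene log2 fold changes were 0.952 for p53 target genes, 0.841 for astrocyte and Bergmann glia, 1.07 for oligodendrocyte lineage, 0.729 for Purkinje cell, 0.701 for GABAergic interneuron and 0.597 for endothelial markers. They were -0.674 for G1/S, -0.882 for G2/M, -0.479 for checkpoint and -0.565 for homologous recombination and Fanconi genes. None of these 10 list calls held with an estimated correlation. The list members were named for their change in the BaxBak comparison, which is part of this difference, so these values were selected on these samples. Single genes with a called difference were Zfp750 (2.47), Fam63b (-2.52), Frmd5 (-2.22), Ubr1 (-1.99) and Chodl (-1.84), of which Frmd5 and Ubr1 did not pass on their brightest probe set (-0.18 and -0.37). Zscan4c, Zscan4f, Zscan4d, Pde6a and Haus2 also had one, with no size given because the first 4 lay under the negative controls in both p53 groups and Haus2 in Atr BaxBak mutants. Of 100 drawn splits of the 12 samples, 10 gave at least the 582 probe sets, the real one included, and the highest other split gave 20600. All 10 kept the real BaxBak groups together (12 drawn splits did), and the highest split without those groups gave 95. Splits that keep these groups hold the BaxBak change inside the difference, so they are not groupings without an effect. The count of such splits therefore does not decide on chance.

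In the BaxBak comparison 1 of the 10 splits of the 6 samples, the real one, gave 37680 probe sets, and the highest other gave 375. For gene lists, 5 of the 10 splits gave at least the real 11, and the highest other gave 12. The splits are too few for a share under 0.05.

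Negative control probe sets were known by their identifiers alone, and the sources used here do not say which sequences they match. They were brighter in Atr BaxBak mutants than in BaxBak controls by 0.325 on the log2 scale (4.43 ± 0.13 against 4.11 ± 0.12, SD, n = 3). The exact permutation p was 0.1 (two-sided, the smallest possible), and the lowest mutant (4.32) lay above the highest control (4.20). Spiked-in poly-A controls were lower by 0.33 in the same mutants (difference of -0.33) and higher by 0.16 in Atr p53 mutants.

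Replication and mitosis genes were lower and markers of other cell types higher in the Atr BaxBak mutants. A brighter array background is argued against as the whole of it, since with that signal as a covariate the median of the G1/S and G2/M genes was -0.756 against -0.948 (median standard errors 0.131 and 0.111). A smaller share of granule cell lineage in these cerebella, which would raise the markers of all other types alike, stays open: the medians of 6 other types lay between 0.503 and 0.852, and their 48 markers did not differ by type in a permutation test that cannot show likeness (p = 0.0993, over genes that are not independent and were selected on these samples). Unipolar brush cell markers (median -0.731) do not decide this, since these cells also arise from the Atoh1 lineage, and only 3 markers were named, of which 1 rose. Postmitotic granule neuron genes, of the granule cell lineage itself, do not decide it either, since they went both ways (4 of 10 higher and 3 lower, median 0.33). The label prefix of the Atr BaxBak mutants was held by 1 group, so genotype and what the prefix marks, such as a litter or processing group, cannot be told apart, and a direct effect of losing Atr in the precursors stays open.

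Early embryonic genes were higher in the same mutants: of 33 such genes on a list written after the Zscan4 values were seen, 9 were named and all 9 rose, 6 of them Zscan4 genes. The lowest mutant mean of these genes lay 0.913 above the negative controls of its array, while the highest BaxBak control lay at -0.502. Background brightness cannot be judged by this, because the genes were named for their change in these samples and listed after the Zscan4 values were seen. Sequence shared between copies of 1 locus stays open, since 7 of the 9, with all 6 Zscan4 genes, lie on 1 chromosome by the code in their identifiers, and each Zscan4 gene shares probe sets of identical values with others of the family. In all 6 p53-background samples the mean of these genes lay under the negative controls of its array, from -1.17 to -0.349 relative to them, so no change can be read there, and 7 of their 31 probe sets passed the test of the difference, a share with no fair comparison because the genes were chosen on their rise. A response that needs p53 was not tested by this: the backgrounds also differ in Bax and Bak, so these cannot be told apart.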

How the results depend on the processing

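The negative control covariate and the filter on the negative control signal were chosen after seeing the data. Quantile normalization, median centring and the label prefix as a random block kept each count of calls within 1.5 times. The block could hardly move a count, since its estimated correlation was 7.32e-05. It does not separate genotype from a label prefix that a single group holds. No paired analysis was possible because the labels give no replicate number shared between groups. Where a value moved, the cause was not tested, except that fewer samples or a term tied to the groups leave less precision. For the Atr effect in the BaxBak background the 37680 probe sets became 59580 with only those above the median signal, 59417 with a trended robust spread, 76028 with array weights, 74040 at an adjusted p under 0.10 and 759 with the negative control covariate. Of named genes called in the BaxBak background 280 of 6145 were left with that covariate. For the Atr effect in the p53 background the 32 probe sets became 8 without moderation, 0 with limma on the comparison's own 6 samples, 21 with sex as a covariate and 10 within the shared label prefix. The 192 named genes called in the p53 background became 103 above the median signal, 42 without moderation, 63 on its own 6 samples, 101 with array weights, 114 with sex, 5 within the label prefix and 124 above the negative controls. In the difference of the Atr effect between backgrounds 582 probe sets became 3788 above the median signal, 2893 with a trended robust spread, 1216 with array weights, 1984 at 0.10, 131 with the negative control covariate and 1175 above the negative controls. The 216 named genes called in the difference between backgrounds became 1167 above the median signal, 913 with a trended robust spread, 438 with array weights, 51 with the negative control covariate and 439 above the negative controls. With an estimated correlation 0 lists were called in any contrast (11, 3 and 10 with the preset one), and fry called 17 in the BaxBak and 0 in the p53 background. The concordance of the 2 Atr effects (r of 0.461) was 0.416 with sex and 0.405 with the negative control covariate. A pair of genes turned sign: Atf3, Atr effect in the p53 background, at -0.0703 above the median signal and on its brightest probe set, and Hist2h2bb, Atr effect in the p53 background, at -0.0956 on its brightest.

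Leaving out 1 sample at a time gave 7554 to 52581 probe sets for the Atr effect in the BaxBak background. Without BaxBak controls 1, 2 and 3 the counts were 15943, 7554 and 14828, and without Atr BaxBak mutants 1, 2 and 3 they were 12013, 15664 and 10334. The 52581 was without Atr p53 mutant 2. Counts of named genes called in the BaxBak background ranged from 2010 to 6518, at 3412, 2010, 3181, 2886, 3417 and 2556 without those 6 samples in that order. For the Atr effect in the p53 background 20 to 54 probe sets passed (20 without Atr p53 mutant 1 or p53 control 2, 54 without p53 control 1). Counts of named genes called in the p53 background ranged from 36 (without p53 control 3) to 709 (without Atr p53 mutant 3), with 39 without p53 control 2, 46 and 79 without Atr p53 mutants 2 and 1, and 124 without Atr BaxBak mutant 1 or 2. The difference of the Atr effect between backgrounds ranged from 167 to 1034 probe sets, and the named genes called in the difference between backgrounds from 61 to 329. These were 281 and 88 without BaxBak control 1, 167 and 61 without 2, 232 and 75 without 3, 226 and 84 without Atr BaxBak mutant 2, 234 and 80 without 3, 223 and 79 without Atr p53 mutant 1, 1034 and 329 without 2, 277 and 88 without 3, 233 and 81 without p53 control 2, and 190 and 68 without 3. Without Atr BaxBak mutant 1 the named genes were 133. Lists called in the p53 background ranged from 3 to 5 (5 without p53 control 1). The concordance of the 2 Atr effects ranged from 0.357 (without Atr p53 mutant 2) to 0.519 (without p53 control 3), and was 0.398 without p53 control 1. Signal over background limits the Zscan4 folds, whose control levels lie under the negative controls, and leaves no fold for Snhg5, Rasal3, Cd2, Usp34, Zfp595 and Apobec3 in the p53 background.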

Other observations

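The histone genes, the contrast between control groups and the tests of chromosome 9, except the one on sex, were chosen only after the result was seen.

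Histone genes, most of which are transcribed during DNA replication, were mostly lower in Atr BaxBak mutants and mostly not called in Atr p53 mutants. In Atr BaxBak mutants 22 of 24 named histone genes were lower by their gene means and 2 higher, with a median of -0.72, on probe sets selected in that comparison. The linker histone gene Hist1h1b stood at -1.28 and Hist1h4m at -1.76. In Atr p53 mutants 21 of the 24 lay above 0, with a median of 0.16, and Hist1h4k (1.66), Hist1h2br (0.63) and Hist2h2bb (0.59) passed over all named genes, while 0 were lower. Of these, Hist1h4k (0.76) also rose in the BaxBak background, Hist1h2br stood at 0.62 there with probe sets going both ways, and its brightest probe set did not pass in the p53 background (0.14). Hist2h2bb, Atr effect in the p53 background, stood at -0.0956 on its brightest probe set. By the test of the difference 8 of the 24 were called lower and 0 higher, although Hist1h2br, which is among the 8, differed by -0.0067 as a gene mean. Most of these genes rest on 1 or 2 probe sets, and near-identical histone genes can share probes. The gene Hist1h2bc was left out because its probe sets carry a second symbol, and 2 of them passed over the whole array in the p53 background, both at 1.79.

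The control groups differed from each other too, although Atr was intact in both. Between p53 controls and BaxBak controls, 368 probe sets were higher in p53 controls and 325 lower (limma). By name, 597 genes were higher and 763 lower. Naming required passing a test that used the same BaxBak controls. Counts of named genes and list members here were therefore selected on these samples and are not independent evidence of direction. Of the 36 named p53 target genes 6 were lower and 0 higher in p53 controls, with a median of -0.06. The 6 were Ephx1 (-0.80), Bloc1s2 (-0.64), Sesn2 (-0.59), Bbc3 (-0.43), Trp53inp1 (-0.33) and Zmat3 (-0.21). Of the G2/M genes 5 of 37 were lower, with a median of -0.15, and 3 of 6 microglia markers were higher and 1 lower. Genotype and label prefix differ together between these groups.

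Of the 32 probe sets that passed in the p53 background, 16 lie on chromosome 9, the chromosome of Atr, by the code in their identifiers (16 of 39191 against 16 of 679880 elsewhere, Fisher's exact p = 1.57e-12, two-sided, over neighbouring probe sets that are not independent). Sex is argued against, as 13 of the 16 still passed with sex as a covariate. The same sequence variants carried along with the Atr allele in both crosses are argued against as the whole account, since over the 16 the median change in the BaxBak background, taken in the direction of the p53 change, was -0.125 against 2.59 (median standard error 0.207). In the BaxBak background 4 of the 16 also passed in the same direction, among them probe sets of Gnb5, Cyb5r4 and Snhg5, against 12 of the 16 elsewhere, so for these 4 such variants and a shared effect of losing Atr cannot be told apart, and for the other 12 a difference of the p53 cross alone, in descent or in expression, stays open and was not tested. At gene level 3.90% of named genes on chromosome 9 and 2.19% elsewhere passed (Fisher's exact p = 0.0381), and the nearest to Atr that passed, Ppp2r3a, lies 47 genes away.

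In the p53 comparison 2 of the 10 splits of the 6 samples gave at least the real 32 probe sets, and the highest other gave 52. For named genes 1 of 10, the real one, gave 192, and the highest other gave 0. For gene lists 7 of 10 gave at least the real 3, and the highest other gave 7. The splits are too few for a share under 0.05.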
